A study of Caenorhabditis elegans with 2 samples.

How the data were processed

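Chromatin immunoprecipitation and sequencing had been carried out with an anti-GFP antibody on whole late embryos of a transgenic Caenorhabditis elegans strain that expresses LIM-6, a LIM homeodomain transcription factor, with a C-terminal GFP and FLAG tag. The strain, OP388, carries the transgene insertion wgIs388 in an unc-119(ed3) background. Per the labels, embryos were hermaphrodite and were taken 5 hours after synchronization by egg bleaching, and 2 libraries were made as biological replicates 1 and 2. Both belong to 1 group, so no contrast between conditions exists, and control libraries were not used here.

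The deposited files are lists of genomic regions in 2 genome builds, ce10 and ce11. For each library, and for both pooled, the authors deposited a relaxed list of peaks and background that served as input to a test of reproducibility by irreproducible discovery rate (IDR). Each relaxed list was made from an alignment together with a control, per the deposited notes on how the lists were derived. The list that passed the IDR threshold of the authors is called the reproducible peaks here. Each region has a signal value given by the authors, and this column was taken here, from the layout of the files, to be the enrichment reported by a peak caller. The values are not whole numbers and were not compared in scale between pooled and single-library lists. A −log10 q-value was also deposited by the authors for each region. The p-value column held no values. Aligner, peak caller and their versions are not given in the sources used here. Read depth per library is likewise not given in the sources used here, so no interval that needs it was computed. In the ce11 files, the 570 reproducible peaks were exactly the 570 pooled regions of highest signal.

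Coordinates are those of the ce11 files, 1-based, and were read against the WBcel235 assembly, which is the same assembly, with Ensembl release 115 gene models. No annotation of ce10 was used, and from the ce10 files only numbers, signals and chromosomes were taken. A summit was assigned to a protein-coding gene when it lay between 1000 bp upstream and 500 bp downstream of an annotated transcript 5′ end, and otherwise to the gene with the nearest 5′ end. The background for every share was the 25135 pooled relaxed regions that overlapped no reproducible peak. Shares were compared by Fisher's exact test, two-sided, over regions, with exact Clopper-Pearson 95% intervals. Regions are not replicates, so these p-values and intervals cover counting error over regions only. Benjamini-Hochberg adjustment was applied within each family (8 motifs, 4 noncoding gene classes, 5 annotation features, 20 gene lists) at a threshold of 0.05.

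Library lists were matched one-to-one at a minimum overlap of 1 bp, best summed rank first, and set against 10 circular shifts of the replicate 2 list. The Spearman correlation over matched regions was tested with 100000 permutations. Motifs were searched on both strands within 100 bp of the summit and in windows of equal width 500 bp to either side, compared by exact McNemar tests. Odds ratios adjusted for GC content used the Mantel-Haenszel method over 10 strata of GC. Summits were called near a tRNA, snoRNA, snRNA or ncRNA gene within 250 bp. Sequence uniqueness was the share of 31-mers in the summit window that occur once in the assembly. Numbers of regions within 20 kb of lim-6 and unc-119 were ranked against 10000 protein-coding gene loci drawn at random.

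The gene lists were fixed before the data were examined, as were the tests, their main settings and the alternatives except those named as chosen later. The lists covered GABA neurons, ASE neurons and left-right asymmetry, RIS and other neurons that express lim-6, neuropeptides, pan-neuronal genes, cholinergic and glutamatergic neurons, cilia and sensory neurons, homeobox genes, nuclear hormone receptors, chemoreceptors, muscle, intestine, hypodermis and cuticle, pharynx, excretory system, germline, ribosomal proteins, histones, translation and mitochondrial housekeeping, and the stress response. Of the listed names, 8 matched no protein-coding gene symbol. Genes tested were the 8189 with a pooled relaxed region in the promoter window. Named genes were lim-6 and unc-119, the genes assigned to the 20 reproducible peaks of highest signal, up to 6 members of a list that passed the threshold and up to 2 of any other list by peak signal, and all members of the GABA, ASE and RIS lists with a reproducible peak.

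The procedures were tested on simulated data. In 50 draws of 570 random pooled regions, 1 of 1000 list tests was called, and the promoter and TAATTA tests each fell under 0.05 in 1 draw. When 15 regions at ribosomal protein promoters were planted, the list was called in all 50 draws, and TAATTA planted in 7% of windows was detected in all 50. The planted sites were added to windows drawn at random, which already had the background share, so smaller differences in TAATTA were not simulated. The 15 regions came on top of any drawn at random, so weaker enrichment of the list was not simulated either. The planted list had 65 tested members. Recovery of short lists, such as the GABA, ASE and RIS lists with 10 to 12 tested members, was not simulated. Alternatives covered the overlap rule, promoter window, motif window, signal threshold, gene assignment, background, genome build, and each library alone, for which as many regions of highest signal were taken from the other library with its own relaxed list as background. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.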

Results

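LIM-6 occupancy was profiled by ChIP-seq of the GFP-tagged protein in 2 libraries of whole late C. elegans embryos. The relaxed list held 21953 regions for replicate 1, 27731 for replicate 2 and 25887 for both pooled, of which 570 were reproducible. Read depth was unknown, so precision is given by the number of regions and by the comparison of the 2 libraries. All values are in the ce11 build unless ce10 is named.

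The first question was which sites had the highest reproducible signal. The highest reproducible peak lay at chromosome III, 8043771 to 8044161, in intergenic sequence 531 bp upstream of K12H4.5, with a pooled signal of 1114 and signals of 563 in replicate 1 and 550.4 in replicate 2. That was 10.8 times the median of the reproducible peaks, 103.3. The next, at chromosome III, 3499868 to 3500218, lay in an intron 968 bp upstream of a 5′ end of M01F1.9 and had a signal of 722, with 344 and 377 in the 2 libraries. From the third peak on, signals were 333 or lower. The third peak lay 558 bp upstream of eel-1, which encodes a HECT-type ubiquitin ligase, but only 25.1% of the 31-mers in its summit window were unique in the genome. Peak 4 was shared by the promoter windows of W03C9.5, mex-1 and rab-7 on chromosome II, with a signal of 324. mex-1 encodes a zinc finger protein of the germline lineage, and rab-7 a small GTPase of late endosomes.

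Further peaks among the 20 highest lay in the promoter windows of ears-2 and uncp-18 (signal 309), Y71G12B.30 and chaf-2 (302), lin-35, the Retinoblastoma ortholog, with vps-51 (301), K01G5.10 and tasp-1 (292), atx-2, the ataxin-2 ortholog, with ecps-1 (271), and atad-3 with nrde-2 (238, in sequence that was 73.1% unique). Mediator subunit gene mdt-8 shared a peak of signal 279 with Y62F5A.12, in sequence of which 12.9% of 31-mers were unique. The ribosomal protein gene rps-24 had a peak of signal 252 in sequence that was 47.4% unique. Peaks at Y92H12BR.2 and Y92H12BR.3, at Y50D4C.5 and at ippk-1 had signals of 273, 241 and 239. The remaining 5 of the 20 lay in no promoter window and were assigned by distance to W03C9.1, cutl-18, F55C5.17, pxn-1 and str-56, with signals of 323, 305, 294, 291 and 242.

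All 570 reproducible peaks overlapped a region in both library lists, and 456 and 457 of them were among the 570 highest of replicates 1 and 2. Their signals in the libraries differed by a mean log2 ratio of -0.09 ± 0.48 (SD over peaks), replicate 1 over replicate 2, with a Spearman correlation across peaks of 0.478. The peaks had been chosen by IDR from these same data, and the relaxed lists include background. The overlap of all 570 is therefore no separate evidence of binding in each library. For example, the peak at Y49G5A.1 had a signal of 54.9 in replicate 1 but 13.9 in replicate 2, under the median of that list, 15.9. Some neighbouring peaks were given the same library region, such as those of pooled signal 241 and 126 at Y50D4C.5 (126.4 and 115.2 in the libraries). The numbers 456 and 457, the SD and the correlation therefore count such regions more than once. Over the whole relaxed lists, 10712 regions matched, which was 48.8% of replicate 1 (95% interval 48.1 to 49.5%) and 38.6% of replicate 2. Shifted lists matched 4341 ± 33.1 regions (SD, 10 shifts), so the observed number was 2.47 times higher. Signals of matched regions correlated with a Spearman coefficient of 0.411 across regions, which are not independent replicates (permutation p = 1e-05, the smallest that the permutations can give). Among the 100 highest regions of each library 66 matched, and among the 5000 highest 2049 did. The ce10 list held 858 reproducible peaks, 1.51 times the ce11 number, although the pooled signals of the 858 highest regions differed between builds by at most 0.582%. The lowest reproducible signal was 80.0 in ce11 and 68.9 in ce10.

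**Figure D1:**
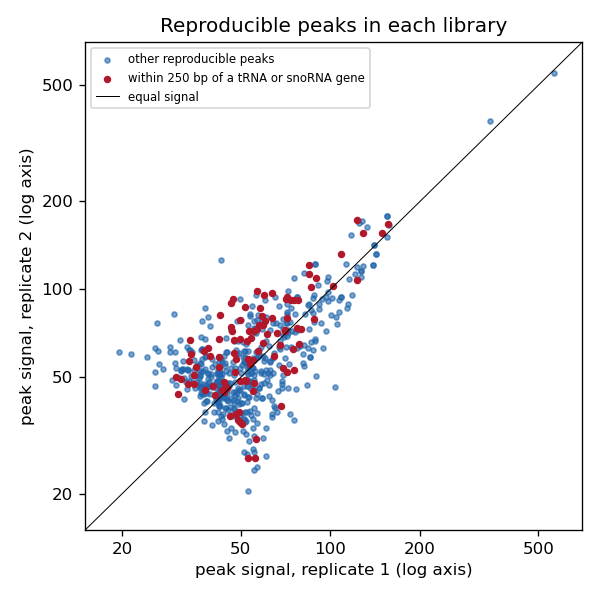
Peak signal in replicate 1 (x axis) and replicate 2 (y axis), as deposited by the authors, on log axes, for the 570 reproducible peaks, with peaks within 250 bp of a tRNA or snoRNA gene in red. The peaks at K12H4.5 (563 and 550.4) and M01F1.9 (344 and 377) stand apart from the remainder in both libraries.

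The second comparison asked where in the genome the reproducible peaks lay. Promoter windows of protein-coding genes held 374 of 570 summits, or 65.6% (61.6 to 69.5%), against 36.7% of the other relaxed regions (odds ratio 3.30, Fisher's exact p = 2.33e-43). Uniform random placement gave 31.6 ± 1.97% (SD, 1000 placements). These windows belonged to 522 genes. Features were read from protein-coding genes only, so a summit in a noncoding RNA gene could count as intergenic or intron. Summits in intergenic sequence made up 70.7% of reproducible peaks and 35.7% of the other regions. Coding exons held 1.40% against 26.4%, introns 25.1% against 32.9%, and 3′ UTRs 0.526% against 2.98%, each with an adjusted exact p of 9.30e-05 or lower. The share in 5′ UTRs, 2.28% against 2.10%, showed no difference detectable at this number of peaks (adjusted exact p = 0.767). Reproducible summits lay a median of 414.5 bp from the nearest 5′ end, compared with 1177 bp, and 75.1% were upstream of it, compared with 46.3%.

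**Figure D2:**
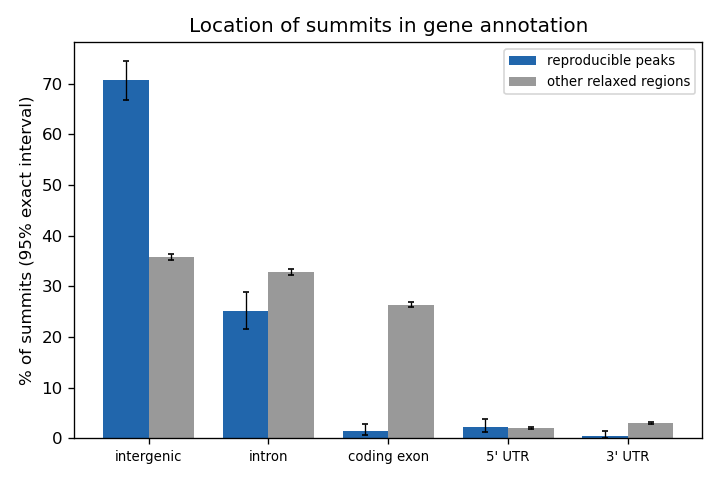
Percent of summits (y axis) in each feature (x axis) for the 570 reproducible peaks and the 25135 other relaxed regions, with bars for the share and error bars for the exact 95% interval over regions. Features are those of protein-coding genes, and noncoding RNA genes were not counted as features. Intergenic sequence held 70.7% of reproducible summits and coding exons 1.40%.

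Chromosome X, which carries lim-6, held 94 reproducible peaks, 16.5% of the total, against 16.7% of the other relaxed regions. The odds ratio was 0.986 (Fisher's exact p = 0.955), so no difference from the autosomes was detected. Among regions at least 90% unique, an alternative chosen after the data were seen, X held 58 reproducible peaks and the odds ratio was 0.688 (Fisher's exact p = 0.00730). That filter also removed 57 of the 59 reproducible peaks near a tRNA gene, most of them on X. The 94 peaks on X, and the odds ratio of 0.986, thus include many peaks at tRNA genes. Chromosome III had the highest density, 8.13 peaks per Mb, and chromosome V the lowest, 4.16 per Mb. The pooled relaxed regions had the same extremes, with 312.4 per Mb on III and 217.8 on V.

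Genes of small noncoding RNAs lay at many reproducible peaks. A tRNA gene was within 250 bp of 59 summits, 10.4% (7.97 to 13.1%) against 1.17% of the other regions, with an odds ratio of 9.79 and an adjusted exact p of 1.05e-33. Summit windows of these 59 peaks were a median of 68.4% unique. Among regions at least 90% unique, which kept 2 of the 59, the call ended, with a tRNA gene at 2 of 464 reproducible peaks and 103 of 22861 other regions (odds ratio 0.957, 95% interval 0.235 to 3.89). Genes of snoRNAs, which guide the modification of other RNAs, were near 42 summits, 7.37% (5.36 to 9.83%) against 0.454%, with an odds ratio of 17.5 and an adjusted exact p of 3.04e-33. Genes annotated as snRNA, among them sls-2.1, sls-2.2 and sls-2.4, were near 5 summits (0.877% against 0.123%, adjusted exact p = 0.00113). The broad ncRNA class was near 124 (21.8% against 8.67%, odds ratio 2.93, adjusted exact p = 8.76e-21). Together, 101 peaks were near a tRNA or snoRNA gene, and 33.7% of these were also in a protein-coding promoter window, compared with 72.5% of the remaining 469. All 5 of the 20 highest peaks without a promoter window had a snoRNA gene within 250 bp, namely W03C9.9, T03F7.8, C51F7.3 and C51F7.4 at the same peak, ZK994.7 and T06C12.16. These snoRNA genes were looked up after the peak values were seen.

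**Figure D3:**
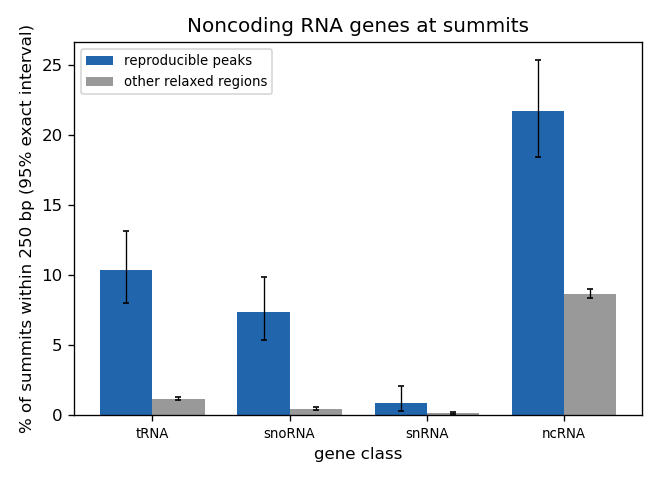
Percent of summits within 250 bp of a gene (y axis) of each noncoding class (x axis) for reproducible peaks and other relaxed regions, with exact 95% intervals over regions as error bars. For tRNA genes the shares were 10.4% and 1.17%, and for snoRNA genes 7.37% and 0.454%.

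Sequence at the summits was compared next, because LIM homeodomains bind sites with a TAATTA core. TAATTA was within 100 bp of 47 summits, 8.25% (6.12 to 10.8%), against 7.57% of the other relaxed regions, and the difference did not pass the test (odds ratio 1.097, Fisher's exact p = 0.522). The same peaks carried it in 10.9% and 9.30% of windows 500 bp to the left and right (exact McNemar p = 0.159 and 0.598). Reproducible peaks had a higher mean GC content, 45.1 ± 7.54% against 41.4 ± 7.99% (SD over regions). Within GC strata, an alternative chosen after the data were seen, the TAATTA odds ratio was 1.57 (1.15 to 2.14) and passed the threshold (Mantel-Haenszel chi-square test, adjusted p = 0.0151). The longer site TTAATTAA was in 2.28% against 1.29% of windows (adjusted exact p = 0.155) and had an odds ratio of 2.87 within GC strata (chi-square test, adjusted p = 0.00141).

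GAGAGA was the fixed motif with the highest share above background. It was at 197 summits, 34.6% (30.7 to 38.6%), against 17.2% of the other regions, 11.2% of left flanks and 10.0% of right flanks, with an odds ratio of 2.54 and an adjusted exact p of 5.81e-22. WGATAR, the site of GATA factors, was less frequent than in the other regions, 21.6% against 28.4% (odds ratio 0.694, adjusted exact p = 0.00114). Within GC strata its odds ratio was weaker, 0.790 (0.645 to 0.968, chi-square test, adjusted p = 0.0406). CACGTG, CAGCTG, TGACTCA and GAARCC had odds ratios of 0.886, 0.889, 1.03 and 0.863, and none passed the threshold, although GAARCC did within GC strata (odds ratio 0.759, chi-square test, adjusted p = 0.0406).

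**Figure D4:**
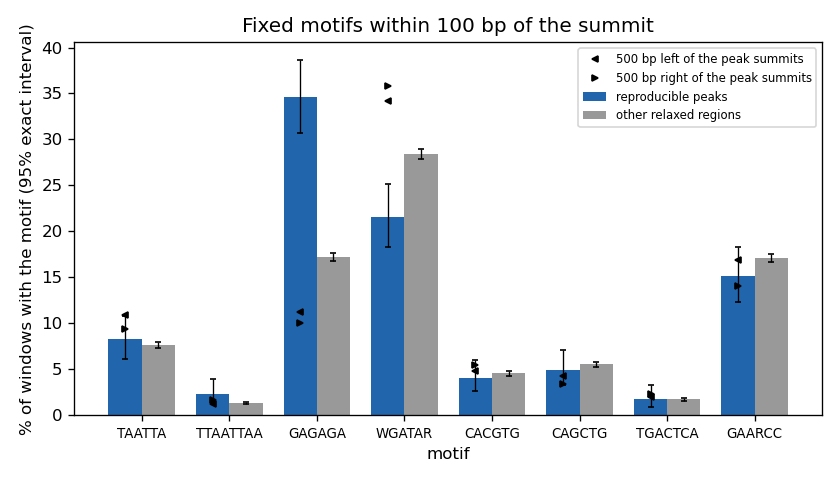
Percent of windows with each motif (y axis) for the 8 fixed motifs (x axis), in bars for reproducible peaks and other relaxed regions with exact 95% intervals over regions, and in triangles for windows 500 bp left and right of the reproducible summits. GAGAGA was in 34.6% of peak windows and 17.2% of background windows, and TAATTA in 8.25% and 7.57%.

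The gene lists asked which kinds of genes had a reproducible peak in the promoter window. Ribosomal protein genes were the 1 list of 20 that passed the threshold, with a peak at 12 of 65 tested members, 18.5% against 6.37% of all tested genes (odds ratio 3.38, adjusted exact p = 0.0143). Its members of highest signal were rps-24 (252), rpl-3 (210.2), rpl-15 (182), rps-23 (152), rpl-43 and rpl-35 (141 each). The rps-23 and rpl-43 peaks lay nearer to the 5′ ends of dpm-3 and Y48B6A.1. The rpl-3 peak, at chromosome III, 3867389 to 3867812, lay 253 bp upstream of its 5′ end, with signals of 97.9 and 110.1 in the 2 libraries. The call ended with peaks of replicate 1 alone (without replicate 2, odds ratio 2.22, adjusted exact p = 0.273) and with assignment to the nearest gene (2.81, adjusted exact p = 0.183).

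None of the lists tied to LIM-6 function differed detectably from the 6.37% of all tested genes that had a peak. In the GABA neuron list the 1 of 10 tested members with a peak was lim-6 itself (odds ratio 1.63), and in the ASE list the 1 of 12 was again lim-6 (1.34). The RIS list had 2 of 12 (odds ratio 2.95), lim-6 and glr-1, which encodes an AMPA-type glutamate receptor subunit. The glr-1 peak lay at chromosome III, 8588716 to 8589139, 286 bp upstream of the gene, with a signal of 92.3 and library signals of 42.8 and 47.8. Adjusted exact p-values for these lists were 0.810, 0.810 and 0.702. Pan-neuronal genes had 3 of 25 members with a peak, led by unc-14 (92.6) and ric-3 (90.03), and cholinergic and glutamatergic genes 1 of 14, glr-1 (adjusted exact p = 0.704 and 0.810). Homeobox genes had 1 of 48, lim-6 (adjusted exact p = 0.810). No peak was at any of 55 neuropeptide genes, 13 cilia and sensory neuron genes, 29 muscle, 9 intestine or 16 pharynx genes (adjusted exact p = 0.243, 1, 0.735, 1 and 0.810).

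Stress response genes had a peak at 4 of 17 tested members, among them hsp-1 (143), a cytosolic Hsp70, and hsp-60 (107), a mitochondrial chaperonin, but the list did not pass (odds ratio 4.55, adjusted exact p = 0.200). It passed when all protein-coding genes were the background (adjusted exact p = 0.0435). Chemoreceptor genes had a peak at 6 of 208, 2.88%, led by sre-23 (235.145) and sre-1 (112.4), with an odds ratio of 0.430 and an adjusted exact p of 0.243. The sre-23 summit lay 621 bp upstream of the gene and within 250 bp of the snoRNA gene ZK265.10. The sre-1 summit lay 897 bp upstream and was nearer to B0495.9. The share of chemoreceptor genes passed the threshold as lower under 3 alternatives, with adjusted exact p of 3.59e-08, 0.0483 and 0.00556 for all genes as background, the wider window and the nearest gene. Nuclear hormone receptors had 3 of 88 (nhr-1 at 103.9, nhr-142 at 102.5), hypodermis and cuticle genes 3 of 70 (col-85 at 149, col-71 at 115.6), histones 2 of 22 (his-67 and his-68, at 1 peak of 96.8), and housekeeping genes 2 of 30 (atp-5 at 126, hsp-60). The excretory list had 1 of 16 (vha-8 at 85.4) and the germline list 1 of 13 (mex-1). Adjusted exact p-values for these 6 lists ranged from 0.810 to 1. The col-85 summit lay within 250 bp of a tRNA gene, in sequence that was 67.8% unique. The col-71 peak was nearer to Y49F6B.2 and had signals of 29.9 in replicate 1 and 82.7 in replicate 2. Peaks at nhr-142, atp-5, hsp-60 and vha-8 were also nearer to the 5′ end of another gene.

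The loci that the transgene carries or marks were examined last. Within 20 kb of lim-6, at chromosome X, 1072452 to 1079452, lay 4 reproducible peaks, above 99.74% of random gene loci. Their signals were 90.3, 188, 127 and 122, and the third had its summit in the 5′ UTR of lim-6, 117 bp downstream of an annotated 5′ end, with library signals of 67.9 and 62.4. The peak of 188, at 1063994 to 1064417, was intergenic and nearest to unc-1. Pooled relaxed regions in the same window numbered 26, against a median of 11 at random loci, which was above 98.92% of them. Replicates 1 and 2 had 25 and 26 regions there, above 99.83% and 97.89% of random loci. In the 50 kb window the pooled number, 42, was above 91.47%. Within 20 kb of unc-119, on chromosome III, there was no reproducible peak, and the 16 pooled regions were above 77.89% of random loci.

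**Figure D5:**
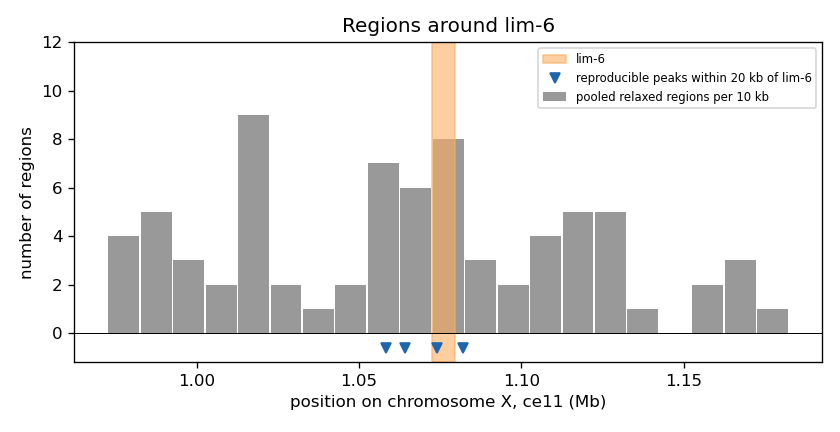
Number of pooled relaxed regions per 10 kb (y axis) by position on chromosome X (x axis, Mb), with lim-6 shaded and the 4 reproducible peaks within 20 kb marked below the axis. The 3 bins from 20 kb before the gene start to 10 kb after it hold 7, 6 and 8 regions, and a bin 60 to 50 kb before it holds 9.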

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

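Settings based on GC strata, on noncoding RNA genes left out, on regions at least 90% unique, on tRNA and snoRNA genes, on GAGAGA and on single libraries at the lim-6 locus were chosen after the data were seen. The shares at promoters, snoRNA genes and GAGAGA kept their direction and side of the threshold in every alternative run, with a promoter share of 52.6 to 75.4% and odds ratios of 12.3 to 25.8 and 1.80 to 2.60. For tRNA genes the odds ratio was 0.957 among regions at least 90% unique, a filter that removed 57 of the 59 peaks, and from 8.37 to 11.9 otherwise. The matched share of replicate 1 was 40.2% at 50% reciprocal overlap, 29.96% with summits within 100 bp and 57.3% for the 1000 highest regions, with rank correlations of 0.442, 0.468 and 0.634. These rules admit fewer or stronger regions by construction. The number of reproducible peaks was 858 in ce10, and the cause was not tested. The odds ratio for X was 1.13 in ce10, and from 0.921 to 1.06 with 1 library left out, without passing the threshold. It was 0.688 and past it among regions at least 90% unique. Most of the 57 tRNA peaks that this filter removed lay on X, such as those assigned to C04A11.5 (78.4% unique), col-181 (65.5%) and egl-17 (66.1%). X had 94 reproducible peaks before this filter and 58 after it. Whether the loss of the tRNA peaks accounts for the lower odds ratio was not tested. For TAATTA it was 0.817 within 50 bp, 0.921 in the 285 peaks of highest signal, 1.01 to 1.02 with 1 library left out, and 1.57 within GC strata, where the difference in GC content was removed. With all genes as background 3 lists were called and with the wider window 2, and the number was 0 to 1 with 1 library left out, 0 being without replicate 2. The cause was not tested. The number of regions at lim-6 was above 91.5% of random loci at 50 kb and above 97.9 to 99.8% in single libraries. Depth could not be weighed, since read counts were not used here.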

Other observations

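The GAGAGA share was lower in groups of peaks with higher signal. With the reproducible peaks divided by signal into 4 groups of 142 or 143, it was 41.96% (exact 95% interval 33.8 to 50.5%) in the lowest group, then 38.03%, 33.8% and 24.5% (17.7 to 32.4%) in the highest. This trend was seen before it was described and was not tested. No class of genes that share a name stem, with at least 8 tested members, passed the Benjamini-Hochberg threshold. The lowest exact p, 0.00376, was for cox genes, which encode cytochrome c oxidase proteins, with a peak at 4 of 11 tested members (adjusted p = 0.187).

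Of the tests that follow, those of TAATTA sites at tRNA and snoRNA genes, of unique sequence at snoRNA genes alone and at tRNA genes alone and of base composition with 6-base palindromes were chosen only after the result was seen, and those of tRNA genes at matched uniqueness and of 8-base palindromes were added after related values were known. For peaks at tRNA and snoRNA genes, the odds ratio within GC strata was 11.6 (9.13 to 14.8), which argues against GC content as the whole cause. TAATTA was within 100 bp of 3.96% of these 101 peaks (1.09 to 9.83%) and of 9.17% of the other 469. Binding through this core as the cause had been set to predict at least 50%. With the core in only 47 of all 570 peaks, that share was out of reach, so the test cannot decide. It shows only that 97 of the 101 peaks lacked the core within 100 bp of the summit. Among regions at least 90% unique the odds ratio of both classes together was 11.2 (7.98 to 15.7), but the filter kept all 42 snoRNA peaks and 2 of 59 tRNA peaks, and apart the odds ratio was 20.8 (14.4 to 30.04) for snoRNA genes, which argues against multi-copy sequence there, and 0.957 (0.235 to 3.89) for tRNA genes. The last value cannot decide, because the 57 tRNA peaks removed all had summits within 50 bp of the gene, as had only 16 of the 103 other regions kept, and from 50% to under 90% unique tRNA genes were at 57 of 76 reproducible peaks and 187 of 1876 other regions, an odds ratio of 27.1 (15.8 to 46.5). The odds ratio of 27.1, with its lower bound of 15.8, was the outcome predicted if the share of repeated sequence were not the cause. The test cannot decide, because this range kept 57 of the 59 tRNA peaks but only 76 of all 570 reproducible peaks. A high odds ratio was therefore favoured by the choice of range, and the share does not give the number of copies. Multi-copy sequence thus stays open for the tRNA peaks, since hardly any lie in unique sequence. A general accessibility of both classes to immunoprecipitation stays open too, and was not tested because control libraries were not used here.

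Around lim-6, one hypothesis is that copies of the gene in the transgene add reads at its native locus. The lists had been made together with a control, and how far it offsets such reads was not tested. The number of pooled regions from 30 to 70 kb beyond the gene was 27, above 79.96% of random loci and under their 95th percentile, which copies limited to the gene's surroundings may produce but binding near the gene would too. The comparison assumes that the insert ends less than 30 kb beyond the gene, and its ends are not given in the sources used here. After regions within 500 bp of a stronger one were removed, the number within 20 kb was still above 98.67% of random loci, so shoulders of strong peaks do not account for it. Binding of LIM-6 to its own locus stays open.

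TAATTA passed the threshold only within GC strata, and whether base composition accounts for this stays open. The highest odds ratio among the other 7 palindromes of 3 A and 3 T was 1.40, for ATTAAT. Their median, 1.25, lay inside the TAATTA interval of 1.15 to 2.14. ATTAAT contains TAAT and ATTA, as TAATTA does, so it is not a control for base composition alone. Among those without TAAT the highest was 1.35, for TATATA, also inside that interval. The longer TTAATTAA, at 2.87 (1.63 to 5.08), lay above all 7. Among 14 palindromes of its own length, of 4 A and 4 T without TAATTA, the highest was 2.79, for AATTAATT, and the median 1.08. AATTAATT also contains TAAT and ATTA, but so do ATTATAAT, at 0.593, and TAATATTA and TATTAATA, each at 0. The highest without TAAT was 2.01, for ATTTAAAT, inside the TTAATTAA interval. The comparison leaves base composition neither excluded nor needed. A separate hypothesis was that sites lie mainly in peaks away from promoters and tRNA or snoRNA genes. TAATTA was in 9 of 129 such peaks and in 38 of the other 441, an odds ratio of 0.795 (0.374 to 1.69), too wide an interval to decide.

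For ribosomal protein genes, a test written before its result asked whether neighbouring noncoding RNA genes carried the call. Without peaks and regions near such genes the odds ratio was 4.13 (2.06 to 8.31), with 10 of 51 members.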
